A study of Mus musculus with 8 samples.

How the data were processed

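Total RNA of crude mitochondria from 8 mouse hearts, 4 controls and 4 Tefm knockouts, had been extracted with a miRNeasy kit and turned into Illumina TruSeq libraries, and paired ends were sequenced on a MiSeq, per the labels' protocols. Whether rRNA was removed and whether the libraries keep strand is not given in the sources used here. Reads from a gene and an overlapping antisense gene therefore cannot be told apart. The series text describes separate mice, so replicates are animals. Per the labels the controls are L/L in the titles and Tefm +/+ in the genotype field, and are taken here as loxP-flanked animals without cre.

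The deposited raw counts per gene are whole numbers. Per the submitters' processing notes, which name tools without role or order, mm10, Bowtie2, SAMtools 1.3.1, bedtools, featureCounts, R 3.3.2 and DESeq2 1.14.1 were used. The deposited normalized signal values equal the raw count times 1 constant per library, with a largest relative deviation of 4.75e-11, so they were used for this check alone. The authors' deposited table gives a mean signal, log2 fold changes with log2 standard errors, a test statistic (a score) and p-values with adjusted p-values. Its settings are not given in the sources used here. Of 49584 features 36 belong to mtDNA, among them merged features for mt-Atp8 with mt-Atp6 and for mt-Nd4l with mt-Nd4 and an added feature mt-7s, and 18277 features held no count in any library.

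Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10, genotype as the term) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05 over 17891 genes. TMM takes most of its weight from nuclear genes by number, and the factors were 0.689 to 0.733 in controls and 1.03 to 1.61 in knockouts. Standard errors are the log2 fold change over the root of F. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, and again with an estimated correlation and with fry. Per-library measures were compared by two-sided exact permutation tests over 70 relabelings, with 0.5 added to counts before slopes. For merged mtDNA features the mean rank of their genes was used, which left 10 heavy-strand mRNA features. Library totals were 21108165 to 27403415 counts, and the biological coefficient of variation was 11.3%. Intervals and floors cover counting error alone, since reads without molecular identifiers are not independent molecules.

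Genes named in the text were chosen by a rule fixed before the data were examined. It takes Tefm, the mtDNA genes, and the 10 largest rises and 10 largest falls among called nuclear genes whose libraries do not overlap between groups, leaving out predicted, clone-named, pseudogene and small RNA genes. Of the 10 falls, 1 is not reported here. From each list it takes up to 4 called members by smallest p, of which at most the first 3 were used. The 29 lists, the tests and the alternatives were also fixed then. Nuclear copies of mtDNA were listed as well, and the 9 of 10 copies found held 7 counts in all. A further 7 lists were written before any value of their members was seen. An eighth, of secreted heart proteins, was written after values of 7 of its 12 members had been seen, 5 of its genes are also in the lists fixed earlier, and it is kept outside the adjustment.

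The test was checked on simulated counts for this comparison, with 50 genes at each of 4 fold sizes changed among 17832 tested. edgeR recovered 84% of genes changed 1.5-fold and 100% at 2-fold, 4-fold and 8-fold, with 12 false calls of 204. The simulation used 1 common dispersion for all genes and both groups. It held few changed genes, no shift in the mtDNA share and no library apart from the others. Its rates may therefore not hold for these data, in which knockouts varied more than controls. Alternatives were DESeq2 1.42.0 (which recovered 76%, 96%, 100% and 100% in the same simulation), RLE factors, library totals, no filter, the replicate number as a block, leaving out each library, nuclear genes alone and mtDNA genes alone. Pairs of replicates differed by more than counting noise in both groups (chi-square per degree of freedom 2.06 to 24.0), so no library was counted as a duplicate. Gene positions are from the GENCODE annotation of GRCm38. Figures were drawn with matplotlib 3.10.9.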

Results

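The series examined the role of TEFM, a factor that keeps the mitochondrial RNA polymerase elongating, in the expression of genes of mitochondrial DNA (mtDNA). Total RNA from crude mitochondria of mouse heart was sequenced from 4 control animals, which carried loxP-flanked Tefm alleles without cre, and from 4 knockout animals, in which cre was expressed from the muscle creatine kinase promoter. This promoter is active in heart and skeletal muscle cells. The libraries of controls 1 to 4 held 26860003, 26290598, 26268804 and 27403415 counts, and those of knockouts 1 to 4 held 25393933, 22463693, 21530663 and 21108165 counts. Crude mitochondria carry RNA from other compartments, and nuclear genes gave 6825329 to 7596951 counts per library in controls and 10331611 to 13204546 in knockouts.

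The count of Tefm (ENSMUSG00000046909.9, chromosome 11, 80136678 to 80142175 in GRCm38, minus strand) did not pass the threshold in edgeR's quasi-likelihood test. Controls held 110, 117, 106 and 144 counts and knockout libraries 166, 233, 230 and 245 counts. On the scaling used for all genes, these were 6.24 ± 0.639 CPM (counts scaled to library size) in controls and 6.86 ± 0.596 in knockouts (SD, n = 4 each). The log2 fold change was 0.14 with a standard error (SE) of 0.11 and an adjusted p of 0.324. Its 95% interval ran from -0.10 to 0.37. Per the labels an exon was flanked by loxP sites, and which exon is not given in the sources used here. The 4 exons of the main transcript make up 7.6%, 35%, 11.5% and 46% of its length. At even coverage and an unchanged transcript level, loss of the shortest exon from every transcript would give -0.11 and that of the longest -0.89. Both lie below this interval, so the count over the whole gene did not show a deletion. Counts per exon are not analysed here, and transcripts of cells without active cre would keep the exon. With library totals as the only scaling the value of Tefm was 1.13 and passed the threshold.

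RNA from mtDNA made up a smaller part of the counts in the knockout libraries. It fell from 73.2% ± 0.731 in controls to 46.3% ± 8.99 in knockouts (SD, n = 4 each; two-sided exact permutation test, p = 0.0286, the smallest p that 70 relabelings allow; 0.0477 after Benjamini-Hochberg adjustment over 5 measures). Knockout replicate 1 stood at 59.3%, and replicates 2 to 4 at 44.2%, 38.7% and 43.1%. With any 1 control left out the exact permutation p was 0.0571, and with knockout replicate 1 left out it was 0.0286. The 11 mRNA features of mtDNA fell from 14.7% ± 0.227 to 6.62% ± 0.280 of the counts (SD, n = 4 each; exact permutation test, p = 0.0286). For this measure knockout replicate 1, at 6.52%, lay among the others. Less RNA from mtDNA and more co-purified RNA of other compartments would each lower these shares, and the shares cannot tell them apart.

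**Figure D1:**
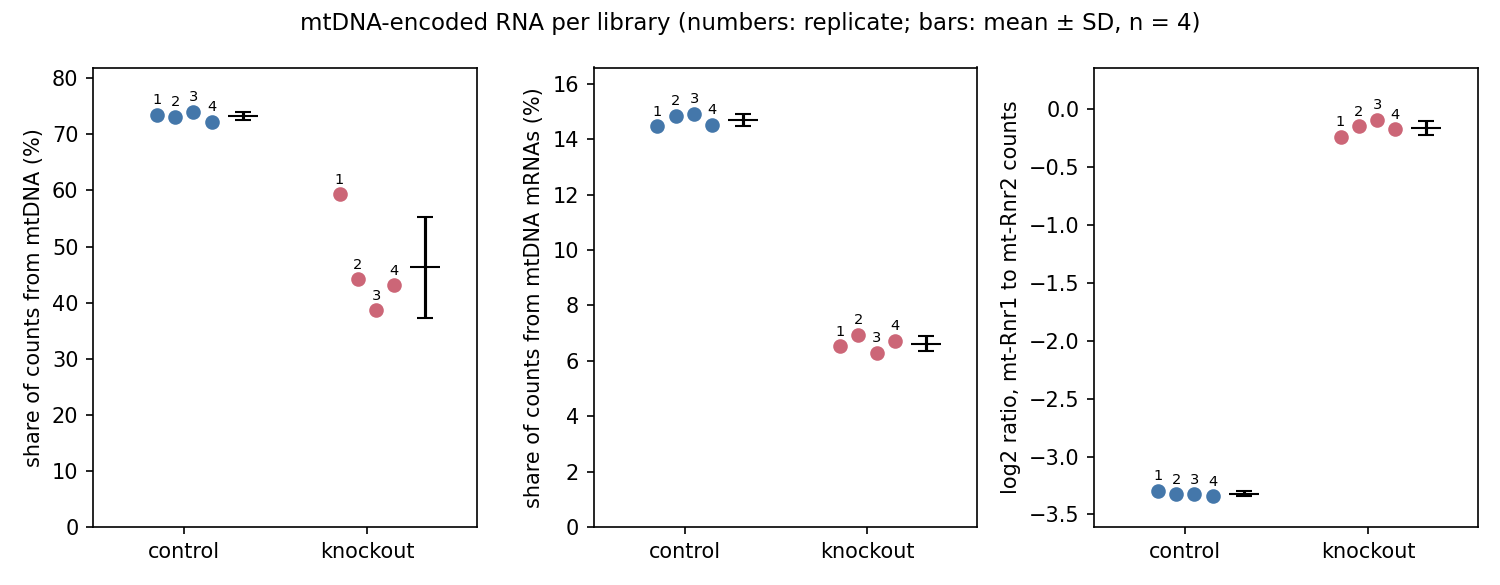
Each point is 1 library, numbered by replicate, with the group mean ± SD beside it (n = 4). The vertical axes give the percent of counts from mtDNA, the percent from its mRNAs, and the log2 ratio of mt-Rnr1 to mt-Rnr2 counts. Knockout replicate 1 lies at 59.3% in the first panel and within the knockout group in the mRNA panel at 6.52%.

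The mRNAs of mtDNA fell in the knockout libraries relative to nuclear RNA, and the 2 rRNAs went in opposite directions. A larger amount of co-purified nuclear RNA would by itself lower every mtDNA feature on this scale, and cannot be told apart from a loss. Ratios between mtDNA features do not depend on that amount. Of the 15 mtDNA features with enough counts to test, 13 fell, 1 rose and 1 did not pass. All 10 heavy-strand mRNA features fell, as counted over all genes tested and when adjusted over the list alone. The largest fall among them was that of mt-Co1, a cytochrome c oxidase subunit (log2 fold change -3.32, SE 0.22, adjusted p = 4.26e-08), from 5.70% ± 0.0786 to 1.09% ± 0.119 of the counts. mt-Nd3 (-2.64, SE 0.16) and mt-Nd1 (-2.24, SE 0.14), which encode complex I subunits, and mt-Co3 (-2.27, SE 0.18), which encodes another cytochrome c oxidase subunit, also fell. The light-strand mRNA mt-Nd6, for a further complex I subunit, fell as well (-3.31, SE 0.16, adjusted p = 1.39e-09). The smallest falls were those of mt-Nd5 (-0.60, SE 0.11, adjusted p = 0.000606) and mt-Cytb (-0.97, SE 0.16, adjusted p = 0.000163), the last mRNAs of the heavy-strand transcript. mt-Nd2 (-1.29), mt-Atp8_6 (-1.65), mt-Co2 (-1.76) and mt-Nd4l_4 (-1.91) lay between, and mt-7s did not pass (0.27, SE 0.22, adjusted p = 0.32), but passed at 1.26 with library totals as the only scaling and at 2.72 with mtDNA genes alone. As a share of all counts mt-Nd5 was 0.486% ± 0.0188 in controls and 0.629% ± 0.0664 in knockouts, and with library totals as the only scaling its value turned to 0.37 and the call of mt-Cytb was lost (-0.02).

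The small-subunit rRNA mt-Rnr1 rose (log2 fold change 0.91, SE 0.26, adjusted p = 0.0108; 0.54 without knockout replicate 1), from 5.32% ± 0.119 to 18.7% ± 3.79 of the counts. The large-subunit rRNA mt-Rnr2 fell (-2.23, SE 0.33, adjusted p = 7.14e-05), from 53.2% ± 0.530 to 21.03% ± 5.20 (SD, n = 4 each). The ratio of mt-Rnr1 to mt-Rnr2, which no scaling moves, was 3.16 log2 units higher in the knockout libraries (two-sided exact permutation test, p = 0.0286), with all 4 knockout libraries above all 4 controls. Whether rRNA was removed is not given in the sources used here, and the cytosolic rRNA feature Rn18s-rs5, chosen after its value was seen, stood at 0.76 (SE 0.14, adjusted p = 0.000448). mt-Rnr1 lies at positions 70 to 1024 and mt-Rnr2 at 1094 to 2675 of mtDNA in GRCm38. When only mtDNA genes were fitted and scaled to each other, mt-Rnr2 stood at 0.13, and 9 mtDNA features that fell in the fit of all genes changed sign.

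**Figure D2:**
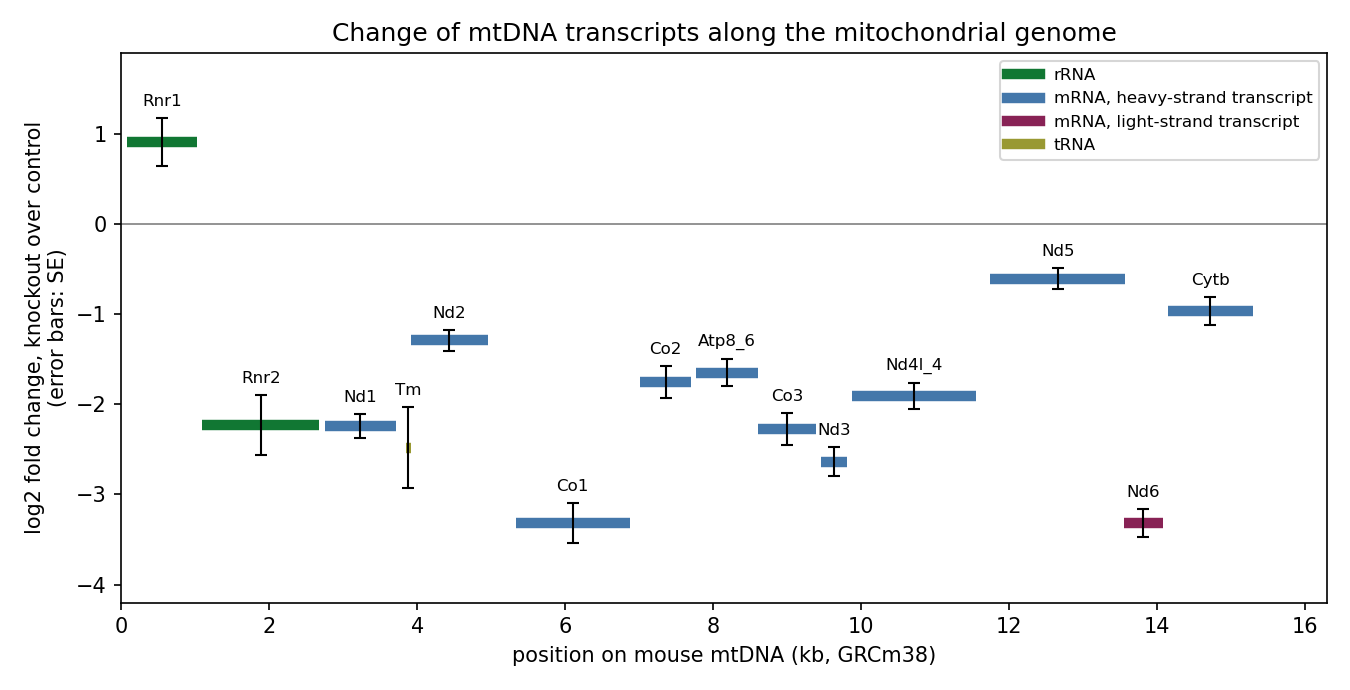
The horizontal axis is the position on mouse mtDNA in kilobases (GRCm38), each bar spans 1 feature, and the vertical axis is the log2 fold change of knockout over control with its SE. mt-Rnr1 lies above 0 at 0.91, and mt-Nd5 and mt-Cytb lie highest among the mRNAs at -0.60 and -0.97; with library totals as the only scaling mt-Nd5 lies at 0.37.

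Whether transcripts farther from the heavy-strand promoter changed more was asked with the slope of log2 counts on gene order. The slope of deviations from the control means was 0.10 log2 units per rank higher in knockouts (SE 0.00237; two-sided exact permutation test, p = 0.0286; adjusted p = 0.0477 over 5 measures), with later mRNAs less reduced. Across the 10 features, which are not independent replicates, Pearson's r of log2 fold change and order was 0.478 (permutation p = 0.163) and Spearman's rho 0.398 (permutation p = 0.253). Without mt-Nd5 and mt-Cytb r was -0.0485 over 8 features and the slope -0.01 (exact permutation test, p = 0.229), so the relation rests on these genes. The slope turned to -0.03 with rRNAs and tRNAs included. The light-strand slope did not differ detectably (0.04, exact permutation test, p = 0.514, adjusted p = 0.514). With 5 instead of 0.5 added to each count it was 0.08 (exact permutation test, p = 0.0286). Apart from mt-Nd6 its features were tRNAs almost without counts, so both values depend on the added count and decide nothing about order.

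The summed rRNAs per mRNA of mtDNA rose by a log2 ratio of 0.57 (exact permutation test, p = 0.0286; adjusted p = 0.0477 over 5 measures), but mt-Rnr2 alone gave -0.22. Knockout replicate 1 had a ratio of 3.02, against 2.37 to 2.43 in the others. The tRNA to mRNA ratio gave 0.72 (exact permutation test, p = 0.0857; adjusted p = 0.107), and 0.97 without knockout replicate 2 (p = 0.0286). The tRNAs were almost undetected: of 22 features 5 held no count in any library, 15 held under 10 counts over the 8 libraries, and the highest count in 1 library was 20. Statements on tRNAs are limited by that depth. mt-Tm, with 66 counts in controls and 19 in knockouts, was the 1 tRNA feature with enough counts to test (-2.48, SE 0.45, adjusted p = 0.000376; -3.22 without knockout replicate 1). Its call was lost when only mtDNA genes were fitted (-0.09).

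Nuclear genes changed widely in both directions. Of 17876 nuclear genes tested, 4668 rose and 4261 fell in the knockout libraries (edgeR, Benjamini-Hochberg FDR 0.05), and 1310 rose and 1192 fell at least 2-fold. Since the RNA was of crude mitochondria, a change in what co-purifies with them cannot be told apart from a change in the heart. In 8106 nuclear genes tested the libraries of the groups did not overlap, which chance gives for 2.86% of genes. These changes are relative to nuclear RNA: with library totals as the only scaling the median log2 fold change moved by 0.99, and 14063 genes rose and 469 fell, so that 96.8% of calls were higher against 52.3%.

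The genes with the largest rises had few or no counts in control libraries. Adm2, which encodes a peptide of the adrenomedullin family, held 0 counts in controls and 587 in knockouts, at least 117-fold higher. Vat1l (at least 68.1-fold), Akr1b7 (at least 46.6-fold), Mei4 (at least 44.8-fold) and Dthd1 (at least 21.6-fold) also held no count in controls. These bounds set 3 counts over the control group as the floor and cover counting error alone. Vmn2r3 held 3 counts in controls and 4235 in knockouts, a ratio of 846 with a 95% counting interval of 289 to 4105. Ostn, the gene of a natriuretic peptide receptor ligand, gave a ratio of 501 (89.7 to 19819), and Bmp10, a growth factor of the atria, 492 (88.1 to 19463). The lone control counts of Ostn and Bmp10 lay in control replicates 1 and 4, and without these libraries Ostn was at least 125-fold and Bmp10 at least 121-fold higher. Without control replicate 2, which held 2 of the 3 control counts, the ratio of Vmn2r3 was 1903 (341 to 75181). The cystine transporter gene Slc7a11 (log2 fold change 7.78, SE 0.56) and the secreted stress factor Gdf15 (7.65, SE 0.59) completed the 10.

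The 10 largest falls were headed by Ces1d, a carboxylesterase that acts on triglycerides (log2 fold change -7.99, SE 0.31, adjusted p = 2.68e-10), and Lrrc15 (-6.19, SE 0.18). Ces1d held 1312 counts in controls and 8 in knockouts, a ratio of 0.00366 with a 95% counting interval of 0.00157 to 0.00722. Of the 8 counts 7 lay in knockout replicate 2, without which its log2 fold change was -10.07. Among them were Aqp4, a water channel (-5.80, SE 0.30), Cpn2 (-5.46, SE 0.35), Frmpd3 (-4.79, SE 0.34) and Cngb3 (-4.74, SE 0.29). Prss55 held 62 counts in controls and 1 in knockouts, a ratio of 0.00967 with a 95% counting interval of 0.000241 to 0.0559. Acsm5 held 100 and 3 counts (ratio 0.018, 0.00365 to 0.0541), and Cacng6, a calcium channel subunit gene, 62 and 3 (ratio 0.029, 0.00582 to 0.0888). Without the library with most of these few counts, Prss55 was at least 25.1-fold lower (knockout replicate 3), and the ratios of Acsm5 and Cacng6 were 0.00823 (knockout replicate 2) and 0.0122 (knockout replicate 1). Lrrc15 and Cpn2 lie 1803 bases apart on the minus strand of chromosome 16. Counting by strand would not separate RNA that runs from 1 gene into the other, so their falls may not be independent.

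Of 22 lists of nuclear genes fixed beforehand, 11 passed FDR 0.05 with limma's camera at a preset correlation of 0.01, 6 of them higher and 5 lower. With an estimated correlation camera passed 0 lists, with 3 at an unadjusted p under 0.05, and limma's fry, which does not compare a list with other genes, passed 12. At least 11 lists were called in 7 of the 35 splits of the 8 libraries, the real one included.

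Genes of the mitochondrial integrated stress response, which is driven by the transcription factors ATF4 and ATF5, rose almost without exception. Of 24 tested members 23 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 3.84 (camera adjusted p = 5.93e-15; adjusted p = 0.0761 with an estimated correlation). Asns, asparagine synthetase, rose 64.3-fold (log2 fold change 6.01, SE 0.12, adjusted p = 1.02e-12). Mthfd2, of mitochondrial folate metabolism, rose 93.6-fold and Trib3 66.3-fold. The member that fell was Vldlr, a lipoprotein receptor gene (-0.45, and 0.53 with library totals). Vldlr, Oma1, Rps2, Cox5b and Slc8a1, and the glycolysis genes Eno3, Pfkm and Hk2, went against their lists and were chosen after their values were seen. The list median was 3.26 in knockout replicate 1 and 3.87 to 4.07 in the others.

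Mitochondrial chaperones and proteases rose in 13 of 20 members and fell in 1, with the same counts when adjusted over the list alone (median 0.38; camera adjusted p = 0.000897; adjusted p = 0.117 with an estimated correlation). The matrix protease gene Lonp1 rose 4.57-fold (2.19, SE 0.09), the chaperone gene Hspa9 2.26-fold (1.18, SE 0.08) and the inner-membrane protease gene Afg3l2 2.18-fold (1.13, SE 0.07). Oma1, another inner-membrane protease gene, fell (-0.50, SE 0.10, but 0.49 with library totals), and 2 members fell without knockout replicate 1. Of 19 glycolysis genes 12 rose and 6 fell (13 and 6 when adjusted over the list alone; median 0.87; camera adjusted p = 0.00915; adjusted p = 0.327 with an estimated correlation). Pfkp, a phosphofructokinase, rose 4.02-fold, the hexokinase gene Hk1 2.82-fold and Gpi1 2.20-fold. Among the 6 that fell were Eno3 (-1.67, SE 0.13), another phosphofructokinase gene, Pfkm (-0.74, SE 0.11), and another hexokinase gene, Hk2 (-0.44, SE 0.09). Genes of the same enzyme thus moved in opposite directions. The glycolysis call was lost with library totals as the only scaling (camera adjusted p = 0.0942). Over the alternatives its adjusted p ran from 6.3e-06 by fry, which does not compare a list with other genes, to 0.327 by camera with an estimated correlation.

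Genes of cardiac stress and the fetal heart rose in 9 of 12 tested members and fell in 1 (10 and 1 when adjusted over the list alone; median 2.13; camera adjusted p = 0.00047; adjusted p = 0.117 with an estimated correlation). Nppa, which encodes atrial natriuretic peptide, rose 46.5-fold (5.54, SE 0.28, adjusted p = 2.16e-09), Ankrd1 8.94-fold (3.16, SE 0.12) and Fhl1 also rose (2.81, SE 0.14). The member that fell was the cardiac actin gene Actc1 (-1.21, SE 0.15), which is also in the sarcomere list. Knockout replicate 1 had a list median of 1.32, against 2.10 to 2.49 in the others.

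Cytosolic ribosomal protein genes rose in 52 of 72 tested members and fell in 1 (53 and 1 when adjusted over the list alone; median 0.57; camera adjusted p = 3.06e-10; adjusted p = 0.33 with an estimated correlation). Rpl3 rose 3.13-fold (1.64, SE 0.08), Rpl4 1.89-fold and Rpl22 1.83-fold, and Rps2 fell (-0.53, SE 0.11, but 0.48 with library totals). These genes have many processed copies that can share their reads, so single values are uncertain. The median was 0.35 in knockout replicate 1 and 0.59 to 0.60 in the others.

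Nuclear genes of the respiratory chain fell by small amounts relative to other nuclear RNA. Complex I subunits fell in 25 of 37 members, and the other 12 did not pass (27 fell when adjusted over the list alone; median -0.37; camera adjusted p = 3.14e-05; adjusted p = 0.761 with an estimated correlation), with Ndufs1 at -0.74 (SE 0.10), Ndufv3 at -0.60 (SE 0.07) and Ndufa3 at -0.59 (SE 0.08), which stood at 0.23, 0.39 and 0.39 with library totals. Of 24 subunits of complexes II to IV 12 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.23; camera adjusted p = 0.00403; adjusted p = 0.831 with an estimated correlation). Cox7a1, a muscle isoform of a cytochrome oxidase subunit, fell (-1.77, SE 0.11), and Cox5b, of the same complex, rose (0.25, SE 0.09). The call of Cox5b was lost without any 1 of the controls and without knockout replicate 1, 3 or 4 (adjusted p = 0.0609 to 0.101), and 1 complex I subunit and 2 subunits of complexes II to IV rose without knockout replicate 2. With library totals as the only scaling the call for complex I was lost and its median turned to 0.61 (adjusted p = 0.967; 2.99e-08 to 0.967 over the alternatives), and the call for complexes II to IV was lost as well (adjusted p = 0.957; 4.7e-05 to 0.957 over the alternatives). Of 16 ATP synthase genes 7 fell and 1 rose, with the same counts when adjusted over the list alone (median -0.29; camera adjusted p = 0.0477; adjusted p = 0.831 with an estimated correlation). The gene that rose was Atpif1, which encodes an inhibitor of the enzyme (1.31, SE 0.13). The call for ATP synthase was lost without control replicate 4 and without knockout replicate 2, 3 or 4 (adjusted p = 0.0574, 0.135, 0.079 and 0.0677; 0.00337 to 0.924 over the alternatives). Knockout replicate 1 gave medians of -0.06, 0.03 and -0.01 for the 3 lists, near the controls. Without it 32, 18 and 10 members fell.

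Genes of calcium handling and ion channels fell in 12 of 18 members and rose in 1 (13 and 1 when adjusted over the list alone; median -0.73; camera adjusted p = 5.38e-05; adjusted p = 0.648 with an estimated correlation). Kcnj3, an inward rectifier potassium channel of the atria, fell (-3.27, SE 0.14), as did the calcium-binding protein gene Hrc (-2.77, SE 0.13) and Kcnd2, another potassium channel gene (-1.76, SE 0.12). Slc8a1, the sodium-calcium exchanger gene, rose (1.03, SE 0.12). With library totals as the only scaling all 5 lists that fell had medians above 0. The call for calcium handling was kept there, lower relative to other genes (camera adjusted p = 1.14e-08).

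**Figure D3:**
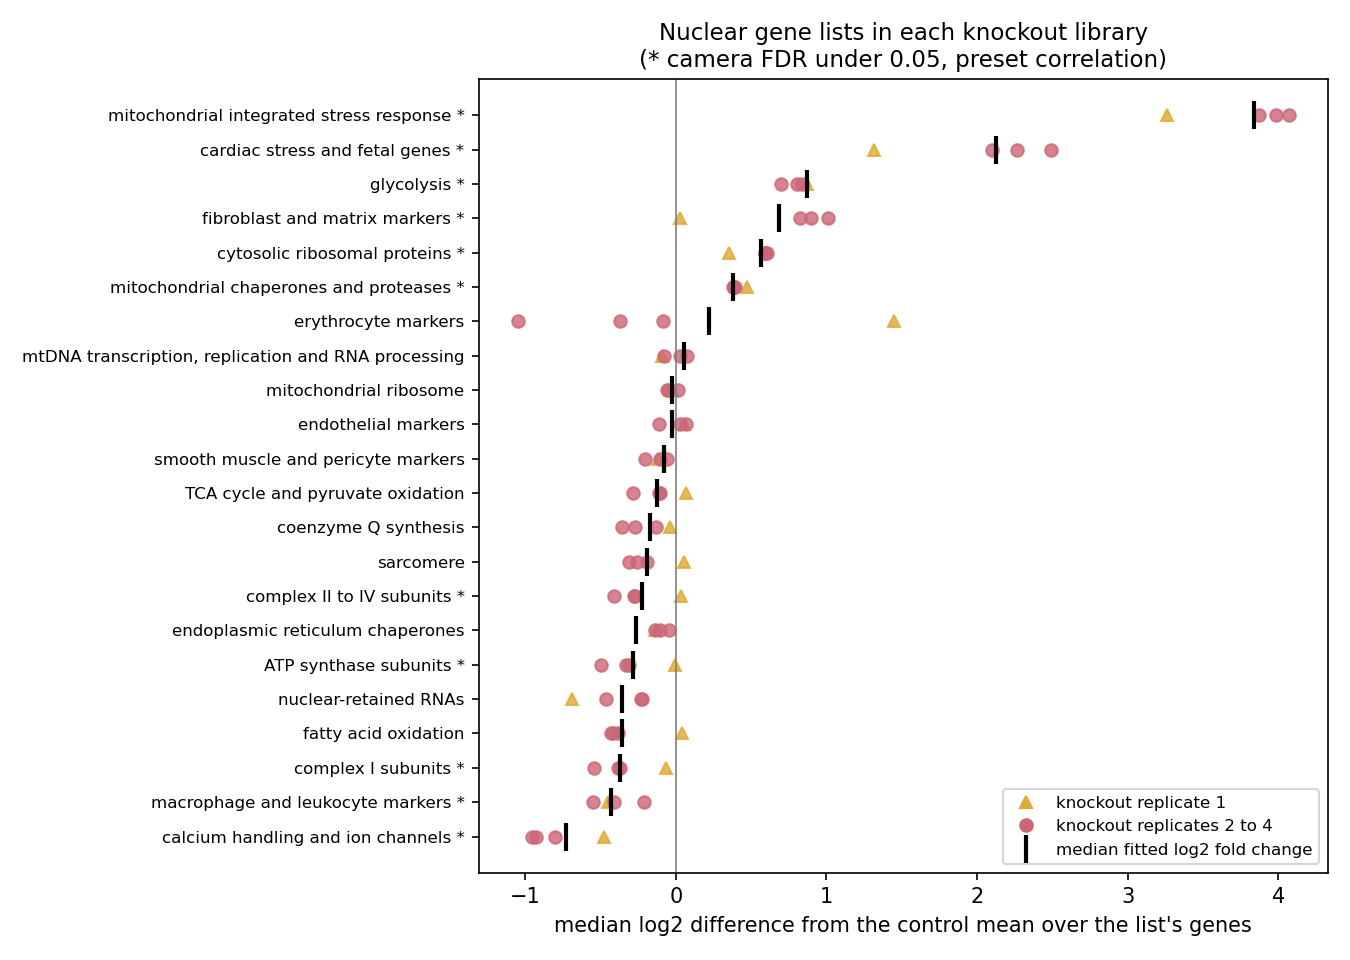
Points give, for each knockout library, the median log2 difference from the control mean over the genes of a list; black ticks give the median fitted log2 fold change and stars mark camera FDR under 0.05 at the preset correlation. The stress response list lies highest at 3.84. Knockout replicate 1 lies near 0 in the fibroblast list (0.03) and at -0.06 for complex I; with library totals the medians of the 5 lower lists lie above 0.

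Fatty acid oxidation (4 rose and 13 fell of 25; camera adjusted p = 0.0547), the sarcomere (4 rose and 9 fell of 20; camera adjusted p = 0.192) and nuclear-retained RNAs (0 rose and 4 fell of 7; camera adjusted p = 0.0547) did not pass as lists. Without knockout replicate 1 fatty acid oxidation passed (adjusted p = 0.00223; 0.00223 to 0.967 over the alternatives), as did the sarcomere (0.0217; 0.0217 to 0.967). The nuclear-retained list passed without control replicate 2 (camera adjusted p = 0.0394), control replicate 3 (0.0444), knockout replicate 3 (0.0475) or knockout replicate 4 (0.0259). Over the alternatives its adjusted p ran from 0.0178 by fry, which does not compare a list with other genes, to 0.745 by camera with an estimated correlation. Acot2, a thioesterase gene, rose 5.13-fold, and Acaa2 (-1.28, SE 0.13) and Cpt2 (-1.06, SE 0.07) fell. With library totals as the only scaling the calls of Cpt2 (-0.06) and of Mterf4 (-0.04) were lost, and Malat1 stood at 0.64. Malat1 lost its call without control replicate 4 (edgeR adjusted p = 0.0519, the highest over the alternatives). Its lowest edgeR adjusted p over the alternatives, 2.65e-05, belongs to the rise with library totals and not to a fall. The TCA cycle list (3 rose and 7 fell of 22), coenzyme Q synthesis (3 and 5 of 13), the mitochondrial ribosome (21 and 22 of 75) and the genes of mtDNA transcription and RNA processing (9 and 8 of 35) did not pass either. In the TCA cycle list 11 members fell without knockout replicate 1, and in the sarcomere list 5 fell without knockout replicate 4. When adjusted over the list alone coenzyme Q synthesis gave 3 and 6, the last list 8 and 8 and the nuclear-retained RNAs 0 and 5. The other lists of this paragraph gave the same counts. Mterf4, of the last list, fell (-1.02, SE 0.10), and Coq8b, of coenzyme Q synthesis, rose (1.65, SE 0.12). The endoplasmic reticulum chaperones (5 rose and 7 fell of 17) had a median of -0.26 and did not pass. Of these chaperones 4 fell without control replicate 4, as did 2 nuclear-retained RNAs.

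Markers of other cells, counted in crude mitochondria and not in whole heart, moved as follows. Fibroblast and matrix markers rose in 11 of 18 members and the other 7 did not pass, also when adjusted over the list alone (median 0.68; camera adjusted p = 0.00374; adjusted p = 0.761 with an estimated correlation). Ctgf rose 10.9-fold, Postn 7.58-fold and Mgp 2.76-fold. Knockout replicate 1 had a median of 0.03, against 0.82 to 1.01 in the others; without it 16 rose. The call was lost with library totals (adjusted p = 0.25; 5.97e-07 to 0.761 over the alternatives). Macrophage and leukocyte markers fell in 6 of 15, and the other 9 did not pass, also when adjusted over the list alone (median -0.43; camera adjusted p = 0.019; adjusted p = 0.761 with an estimated correlation), with Cd74 at -2.06 (SE 0.19). That call too was lost with library totals (adjusted p = 0.0942; 0.00345 to 0.761 over the alternatives). Endothelial (2 rose and 3 fell of 14) and smooth muscle markers (1 rose and 3 fell of 9) did not pass as lists, with the same counts when adjusted over the list alone. Of the smooth muscle markers 2 rose without control replicate 3, knockout replicate 1 or knockout replicate 2. Cldn5, of endothelial junctions, rose (0.93, SE 0.08), and Kdr, an endothelial growth factor receptor gene, fell (-0.41, SE 0.08) but stood at 0.60 with library totals. Acta2, smooth muscle actin, fell (-1.07, SE 0.15), a call lost with library totals (-0.11). Of 6 erythrocyte markers edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Their median was 1.45 in knockout replicate 1 and -1.05 to -0.09 in the others, and 2 fell once that library was left out. Of 7 adipocyte markers 0 had enough counts to test.

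The authors' deposited table of their DESeq2 comparison held 4605 genes higher and 3982 lower at an adjusted p-value under 0.05, of 24245 genes with one. Of the genes tested in both, 7990 were called in the same direction in both, 953 in edgeR alone, 15 in the authors' deposited table alone and 0 in opposite directions. In the authors' deposited table Tefm stood at 0.15 and mt-Co1 at -3.17.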

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

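The tests of the 3 patterns weighed at the end were chosen only after the results were seen. In 252 groups of 4 libraries, 25 held a library far from the others. Its gap to the nearest, as a part of the group's range, was above Dixon's 95% critical value. Chance gives this in about 1 in 20 independent groups. That rate does not apply here, since the groups share libraries and some held no count. A lone count also gives a gap of 1 by construction. Of the 25 flagged groups 14 were knockout groups, with knockout replicate 1 far out in 12, and 11 were control groups.

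Knockout replicate 1 lay above the other knockouts in the rRNA to mRNA ratio of mtDNA (gap 0.896 of the range), mt-Nd1 (0.929), Uqcr11 (0.83), Atp5j (0.873), Acaa2 (0.86), Tnni3 (0.94) and the fatty acid oxidation median (0.903). It lay below them in Adm2 (0.881), Gdf15 (0.888), Dnajb9 (0.911), Cd74 (0.893) and the median of cytosolic ribosomal proteins (0.951). Knockout replicate 3 held the lone count of Prss55 (1), and knockout replicate 4 was high in Malat1 (0.899). Control replicate 1 was low in mt-Nd6 (0.914) and Des (0.835), held the lone Ostn count (1), and was high in the fatty acid oxidation median (0.841). Control replicate 2 was low in Pfkp (0.911) and in the TCA cycle median (0.85) and high in Nppa (0.949). Control replicate 3 was low in Cacng6 (0.935). Control replicate 4 held the lone Bmp10 count (1) and was low in Rpl3 (0.913) and in the fibroblast median (0.844). The mt-7s feature, outside the mRNA, rRNA and tRNA measures, had a log2 ratio to mtDNA mRNA 2.37 higher in knockouts (exact permutation test, p = 0.0286, outside the 5 adjusted measures).

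The first pattern is the rise of mt-Rnr1 beside the fall of mt-Rnr2. For the difference between the 2 rRNAs, library scaling is argued against by their ratio. It differed by 3.16 log2 units without overlap. The ratio does not fix the direction of each rRNA: relative to mtDNA mRNA, mt-Rnr2 differed by -0.22 log2 units with overlapping libraries. A loss that grows with distance from the promoter was not detected among mRNAs, and is not excluded. The slope over mRNAs was 0.10 (SE 0.00237), but this rests on mt-Nd5 and mt-Cytb. Without these genes the slope was -0.01 (SE 0.00792, exact permutation test, p = 0.229), which cannot decide the question. The slope of -0.03 with rRNAs and tRNAs included holds the pattern itself and decides nothing. Single tRNA features, picked after their values were seen, held few counts. mt-Tf, at positions 1 to 68 before mt-Rnr1, held 0 counts in controls and 25 in knockouts. Beyond mt-Rnr2, mt-Tl1 held 36 and 4 and mt-Ti 28 and 1, but mt-Tw, farther on, held 9 and 26. Counts this low cannot decide the question either. Uneven removal of rRNA may contribute: Rn18s-rs5, a cytosolic rRNA feature chosen after its value was seen, was higher too (0.76, SE 0.14, edgeR adjusted p = 0.000448), and mt-Rnr1 counts per mt-Rnr2 count were 0.166 of the ratio of gene lengths in controls and 1.48 of it in knockouts. Whether rRNA was removed is not given in the sources used here, so this stays open beside an effect of genotype, which was not tested separately.

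The second pattern is the smaller fall of mt-Nd5 and mt-Cytb than of the other heavy-strand mRNAs. Scaling is argued against by their ratio to the others, 1.52 log2 units higher in knockouts without overlap. A single library is argued against as well, since leaving out any 1 of the 8 moved that difference by a factor of at most 1.02 (1.49 to 1.55). An effect of genotype may remain as a hypothesis, found and tested on the same data. Differences in read coverage along the transcript were not tested. Whether the libraries keep strand is not given in the sources used here, so RNA of the opposite strand may add to these 2 features, which was not tested either.

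The third pattern is the Tefm count, which was not lower in knockouts. An exchange of single libraries between the groups is argued against by the mtDNA mRNA share, whose lowest control lay 7.54 percentage points above the highest knockout. An exon lost from transcripts at an unchanged level would at even coverage give -0.11 for the shortest exon and -0.89 for the longest, and the lower 95% limit of the Tefm log2 fold change, -0.10, lies above both. Even coverage and loss from every transcript are assumed and counts per exon are not analysed here, so this bound excludes nothing. The cre promoter is active in muscle cells, and the part of Tefm RNA from other cells was not measured. Uneven coverage over the exons, a higher level of transcripts that lack an exon and intact transcripts of other cells may each account for the count. They cannot be told apart, since which exon was deleted is not given in the sources used here.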

How the results depend on the processing

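The counts of changed list members, the further lists and the ratios of low-count genes leaving out 1 library, the slope without mt-Nd5 and mt-Cytb, and the family of 8 further lists, were tests chosen only after the data were seen; the other alternatives were planned. The first gave 2 erythrocyte markers against 0 and 11 lower members of the TCA cycle list against 7, both without knockout replicate 1. With library totals as the only scaling 14532 nuclear genes changed (14063 higher, 469 lower), and 5137 nuclear calls were shared in direction with TMM; the shift of 0.99 in the median is the cause by construction, since mtDNA takes a smaller share in knockouts. Other settings gave 8127 to 9611 changed nuclear genes, the highest without knockout replicate 1. Library totals also turned the sign of mt-Nd5 (0.37), Ndufv3 (0.39), Ndufs1 (0.23), Ndufa3 (0.39), Uqcr11 (0.11), Cox8b (0.077), Atp5e (0.30), Atp5j (0.33), Mrpl18 (0.13), Coq10a (0.37), Coq9 (0.38), Sucla2 (0.45), Kcnq1ot1 (0.47), Rian (0.33), Malat1 (0.64), Kdr (0.60), Tie1 (0.66), Notch3 (0.72), Ptprc (0.44) and Lyz2 (0.37), and ended the calls of mt-Cytb (-0.02), Mterf4 (-0.04), Cpt2 (-0.06), Tnni3 (-0.05) and Acta2 (-0.11), while mt-7s (1.26) and Tefm (1.13) passed. They also turned the direction of complex I (adjusted p = 0.967) and ATP synthase (0.924). Scaling to mtDNA genes alone turned mt-Rnr2 (0.13), mt-Nd1 (0.20), mt-Nd2 (1.17), mt-Co2 (0.65), mt-Atp8_6 (0.78), mt-Co3 (0.14), mt-Nd4l_4 (0.52), mt-Nd5 (1.85) and mt-Cytb (1.45), which its construction shows, as the measure is then relative to other mtDNA genes. With an estimated correlation 0 gene lists passed in camera (3 at an unadjusted p under 0.05, 12 by fry), and with library totals 5. The heavy-strand mRNA order slope was -0.0332 with rRNAs and tRNAs included, the light-strand gene order slope -0.0598 over tRNAs alone and 0.0809 with 5 added to counts, the mtDNA tRNA to mRNA log2 ratio 1.25 as a mean of per-gene values and 0.452 to 0.971 leaving out 1 library, and the mtDNA rRNA to mRNA log2 ratio -0.217 for mt-Rnr2 alone; the cause was not tested. Leaving out 1 library gave a difference in share of counts from mtDNA of -31.2 to -24.4; without any 1 control the exact permutation p was 0.0571, above the 0.0286 that 35 relabelings allow, because 1 other relabeling, with knockout replicate 1 among the controls, gave a larger difference (27.6 to 28.01 points). The replicate numbers did not pair the samples (correlations of same-numbered deviations 0.06, 0.00, 0.03 and 0.20, and only replicate 4 matched its own number best). With the replicate block 8819 nuclear genes changed, and the mtDNA share (-26.9), heavy-strand slope (0.1004) and rRNA ratio (0.567) kept their values with an exact p = 0.125, the smallest that sign flips of 4 pairs give. The block also passed the nuclear-retained RNAs (adjusted p = 0.038) and changed no other list call. Depth limits the tRNAs, of which 15 of 22 held under 10 counts.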

Other observations

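Tests chosen only after the result was seen are those of the secreted heart protein genes and those leaving out 1 library or with library totals. Members named here were taken by smallest p, or because they went against their list, after their values were seen. Of 7 further lists written before any value of their members was seen, 4 passed camera at the preset correlation, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). That 0 depends on the family of lists: with the eighth list, described further on, included, 2 of 8 passed with an estimated correlation, that list and the cytosolic synthetases (adjusted p = 0.04 and 0.0441), and the choice to leave it out was made with that effect known. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, rose in 18 of 20 members, also when adjusted over the list alone (median 1.49; camera adjusted p = 1.77e-11; adjusted p = 0.0771 with an estimated correlation), with Sars at 2.84 (SE 0.08) and Eprs at 2.29 (SE 0.07). Targets of NRF2, a transcription factor of the oxidative stress response, rose in 13 of 14, also when adjusted over the list alone (median 1.18; camera adjusted p = 4.66e-07; adjusted p = 0.0874 with an estimated correlation), with Gclm at 1.93 (SE 0.14) and Nqo1 at 2.02 (SE 0.16). Targets of p53 rose in 8 of 12 and fell in 1, Ccng1 (-0.66, but 0.31 with library totals; 9 and 2 when adjusted over the list alone; median 0.57; camera adjusted p = 0.0221; adjusted p = 0.217 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor gene, at 2.73 (SE 0.11), and 2 fell without knockout replicate 1.

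Interferon-stimulated genes went against the rise written down for them: 14 of 16 fell (15 when adjusted over the list alone), with a median of -0.84 (camera adjusted p = 3.46e-05; adjusted p = 0.217 with an estimated correlation) and Ifih1 at -0.88 (SE 0.11). With library totals as the only scaling their median was 0.16 and Ifih1 stood at 0.12. Macrophage and leukocyte markers moved the same way (0 rose and 6 fell of 15, median -0.43), with Cd74 at -2.06 (SE 0.19). Mitochondrial synthetases (1 rose and 5 fell of 17, and 0 and 3 when adjusted over the list alone; camera adjusted p = 0.556), cell cycle genes (1 rose and 1 fell of 11; 0.556) and cholesterol synthesis (5 rose and 4 fell of 16; 0.977) did not pass. Of the mitochondrial synthetases 2 fell without control replicate 4 and 3 without knockout replicate 2, and Rars2, the 1 that rose, kept its call only without control replicate 4 or knockout replicate 3. Of the cholesterol synthesis genes 2 fell without control replicate 1 or 2, and 3 rose without control replicate 4. Leaving out any 1 library changed no camera call of the 7 lists. The bound written beforehand, which took a missed threshold as evidence against a rise, was too loose, since a missed threshold does not exclude a small rise. The cell cycle median was -1.15 in knockout replicate 1 and -0.11 to -0.06 in the others.

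The eighth list, of 12 genes for secreted heart proteins, was written after values of 7 of its members had been seen, and 5 are also in the lists fixed earlier. It is therefore not independent evidence and stays outside the adjustment. Of its members 10 rose, and its unadjusted camera p was 6.7e-08 (0.005 with an estimated correlation); Nppb, of smallest p among its members not named before, stood at 3.15 (SE 0.20).

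Counts were also taken over the 35 splits of the 8 libraries into 4 and 4. For changed nuclear genes 1 split, the real one, gave as many as 8929, the highest other being 0 in edgeR (2034 at an unadjusted p under 0.05, against 9998). For changed mtDNA features 1 split, the real one, gave as many as 14, the highest other being 0 in edgeR (1 at an unadjusted p under 0.05). The real split thus ranked first for both counts, and 1 of 35 is the smallest share these splits allow. The other splits mix the genotypes, which adds the group difference to the spread within groups. The ranking therefore does not exclude chance. For gene lists 7 splits gave at least the real 11, the highest other being 12, so chance is not excluded for the number of lists past the threshold.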
